A study of Mus musculus with 12 samples.

How the data were processed

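RNA was measured from sorted mTEChi and mTEClo of an Aire line and a Brg1 line, each with wild-type and knockout mice, on 12 biotin-labelled Affymetrix arrays. Per the labels' protocols, thymi were digested, enriched for stroma and sorted, and RNA was extracted with Trizol LS and purified on columns. The deposited table gives 1 intensity on a linear scale for each of 33732 probe sets on each array. The submitters' processing notes name RMA, Affymetrix Expression Console and Transcriptome Analysis Console, with no versions, roles or order. RMA as commonly run corrects background, sets arrays to common quantiles and summarises probes by median polish; whether all 12 arrays were normalized together is not given in the sources used here. Every deposited intensity equals 2 raised to a number with 2 decimals, so the values carry a rounding step of 0.01 on the log2 scale. Array medians lay between 5.07 and 5.32 on that scale, so the deposited quantiles were close but not identical between arrays. No detection p was used, so the lowest level that lies above background is not known, and a fold change of a gene that is dim in one group is compressed by that background.

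Intensities were turned into log2 values with no pseudocount and no further normalization. Probe sets were named through the platform annotation: 23491 had 1 gene symbol, 1811 had several and 8430 had none in that table. Where a gene had several probe sets, the one with the highest mean over the 12 arrays was used, which set 1337 aside and left 22154 genes. Of these, 21968 had an Entrez identifier in a RefSeq gene table of assembly GRCm38.p6, which was used only for names, so no coordinates are given.

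Samples were grouped by the genotype, cell type and replicate number in the labels, into 8 groups. Fits were made in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) as 1 model of 8 group means over all 12 arrays, with 4 residual degrees of freedom, a prior of 3.46 degrees of freedom, and Benjamini-Hochberg adjusted p under 0.05 over the 22154 genes, two-sided. SE is the moderated standard error of limma. The mTEClo groups have 1 array each, and each lone array was assumed to vary like the mTEChi groups. Contrasts were each knockout against its wild type in mTEChi and in mTEClo, mTEChi against mTEClo averaged over both wild types, differences between those effects, and the wild types of both lines. Arrays in all groups share replicate numbers, and a fit with the number within each line as a block was set beside each result; it has 2 residual degrees of freedom. The lines share no array. Groups had at most 2 arrays; other splits of the samples were not counted and no test for a sample far from its group was made.

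Gene lists, comparisons, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule names Aire, Smarca4, Ins2 and Spt1, then up to 10 genes with the largest rise and 10 with the largest fall among those that passed with arrays that do not overlap between groups (5 each way for other comparisons). It leaves out predicted genes, clone names, microRNAs, small nucleolar and ribosomal RNAs and olfactory and vomeronasal receptors. It also allows up to 4 members with the smallest adjusted p of each list described. Some list members named below lie outside these 4, and their mention was chosen after their values were seen. The 28 lists cover mTEC maturation and subtypes, cortical TECs, other cells a sort could hold, SWI/SNF subunits, Aire partners, signalling, 9 peripheral tissues and their union, the cell cycle, stress responses and sex-linked genes; the last were kept out of the tests. Lists were tested with limma camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over 27 lists per comparison. For mTEClo, the percentile of a list's median among 10000 random lists of the same size and matched mean expression was added. Overlaps of calls used a two-sided Fisher's exact test.

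The steps were tested on simulated arrays with known changes in the Aire contrast over 22154 genes. A first version, which took each gene's own residual spread as its true spread, recovered 0 of 100 genes changed by 1 and 0 of 100 changed by 2 on the log2 scale, although the mean estimates were 1.05 and 2.01. Its prior degrees of freedom were 2.50 against 3.46 in the real data, so its variances differed more between genes. Whether this caused the 0 recoveries was not tested. A second version drew variances from the prior that limma had fitted to the real arrays with a block common to both lines. The main fit of these simulated arrays gave 3.52 prior degrees of freedom. In that version the percent of 50 genes recovered was 0 at 1, 36 at 2, 78 at 3 and 96 at 5 on the log2 scale, with 0 false calls. With the replicate block it was 4, 86, 100 and 100, with 7 false calls. The simulated arrays kept a difference between array numbers common to all groups. The block removes it by construction, so its gain over the main fit was fixed by the simulation and is no evidence about the real arrays. For a simulated list of 16 genes shifted by -0.5, camera gave p = 1.05e-08, p = 0.0116 with an estimated correlation and p = 0.0182 with fry, and of 100 unshifted lists 3, 1 and 1 fell under 0.05.

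Alternatives were the replicate block, the spread from only the arrays compared or from the 6 arrays of a line, quantile normalization again, centring on array medians, filters on dim genes, all probe sets, a trended prior, array weights, a 2-fold minimum, leaving out each array, and the other list tests. Added after seeing the data were a block common to both lines, leaving out the genes that differ between arrays numbered 1 and 2, leaving out arrays in the list tests and the overlap, tests of the set of genes lower without Aire, tests in mTEClo of the genes higher in mTEChi, and fits of each line alone for the effects on those genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.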

Results

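Gene expression was measured on 12 single-channel Affymetrix mouse gene arrays of medullary thymic epithelial cells (mTECs), the thymic stromal cells that express many genes otherwise restricted to peripheral tissues. The cells were described as coming from C57BL/6 mice aged 4 weeks. They were sorted as CD45-negative, Epcam-positive, UEA-positive, Ly51-low cells into MHC class II high (mTEChi) and MHC class II low (mTEClo) fractions. A pair of mouse lines was studied, one carrying a loss of Aire, the transcriptional regulator of peripheral tissue antigens in mTECs, and one carrying a loss of Brg1, the ATPase of the SWI/SNF chromatin remodelling complex that is encoded by Smarca4. Each line had a wild-type and a knockout group. Each of the 4 mTEChi groups had 2 arrays and each of the 4 mTEClo groups had 1 array. The labels do not say that replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical. Array medians lay between 5.07 and 5.32 on the log2 scale, and the small number of arrays limits the precision.

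The targeted genes were examined on every array first. The Smarca4 probe set read 6.13 and 6.89 (log2 intensity) in Brg1+/+ mTEChi and 5.88 and 5.44 in Brg1-/- mTEChi, a difference of -0.85 (SE 0.331, n = 2 and 2, adjusted p = 1) that did not pass the test. It read 5.95 in Brg1+/+ and 5.47 in Brg1-/- mTEClo. In the Aire line it read 6.15 and 6.53 in Aire+/+ mTEChi, 6.31 and 6.42 in Aire-/- mTEChi, and 6.40 and 6.11 in Aire+/+ and Aire-/- mTEClo. The Aire probe set read 8.04 and 8.80 in Aire+/+ mTEChi and 9.01 and 9.73 in the arrays labelled Aire-/- mTEChi, a difference of 0.95 (SE 0.539, adjusted p = 1) with the knockout arrays the higher. Aire read 7.96 and 9.50 in Brg1+/+ mTEChi, 8.35 and 8.75 in Brg1-/- mTEChi, and 6.43, 6.72, 6.53 and 6.82 in Aire+/+, Aire-/-, Brg1+/+ and Brg1-/- mTEClo. The position of either probe set relative to the deleted part of its gene is not known here, so neither reading checks the genotype labels, and the groups below are those the labels name.

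The first comparison asked which genes in mTEChi depended on Aire. In the arrays labelled Aire-/-, the Paneth cell defensins Defa21 and Defa22 fell furthest, by 7.92 (SE 0.286, adjusted p = 9.56e-05) and 7.62 (SE 0.267, adjusted p = 9.56e-05) on the log2 scale (n = 2 and 2), Defa21 from a mean log2 intensity of 11.91 to 4.00. The demilune cell proteins Dcpp2 and Dcpp1 fell by 7.16 (SE 0.409) and 7.02 (SE 0.465), the major urinary protein Mup6 by 7.07 (SE 0.622) and the cornified envelope gene Lce3a by 6.34 (SE 0.4). The odorant-binding protein gene Obp2a changed by -5.98 (SE 0.59), Retnla by -5.70 (SE 0.91), Omt2b by -5.70 (SE 0.74) and the cystatin Cst9 by -5.69 (SE 0.484). Tafa1 and Dusp15 rose by 2.15 (SE 0.255, adjusted p = 0.013) and 1.85 (SE 0.269, adjusted p = 0.0321). The Defa, Dcpp, Mup and Obp genes belong to gene families whose members can be similar in sequence, so a probe set may read several members. Probe sequences were not analysed here.

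In all, 176 of 22154 genes passed the test, 171 of them lower and 5 higher. The 171 had a median log2 difference of -3.34, from -7.92 to -1.51. In each of the 176 genes both knockout arrays lay on the same side of both wild-type arrays. The other 3 genes that rose, chosen for mention after their values were seen, were 1700003P14Rik (3.28), Gm5086 (3.07) and Olfr1136 (2.84). The count rested on few arrays: without Aire+/+ mTEChi replicate 1 it was 53, without replicate 2 it was 67, and without either Aire-/- mTEChi replicate it was 70. With the replicate number as a block, 531 genes passed (465 lower and 66 higher), among them all 176. Leaving out 1 array also left the array numbers unbalanced between genotypes, so those lower counts can hold the difference between numbers.

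**Figure D1:**
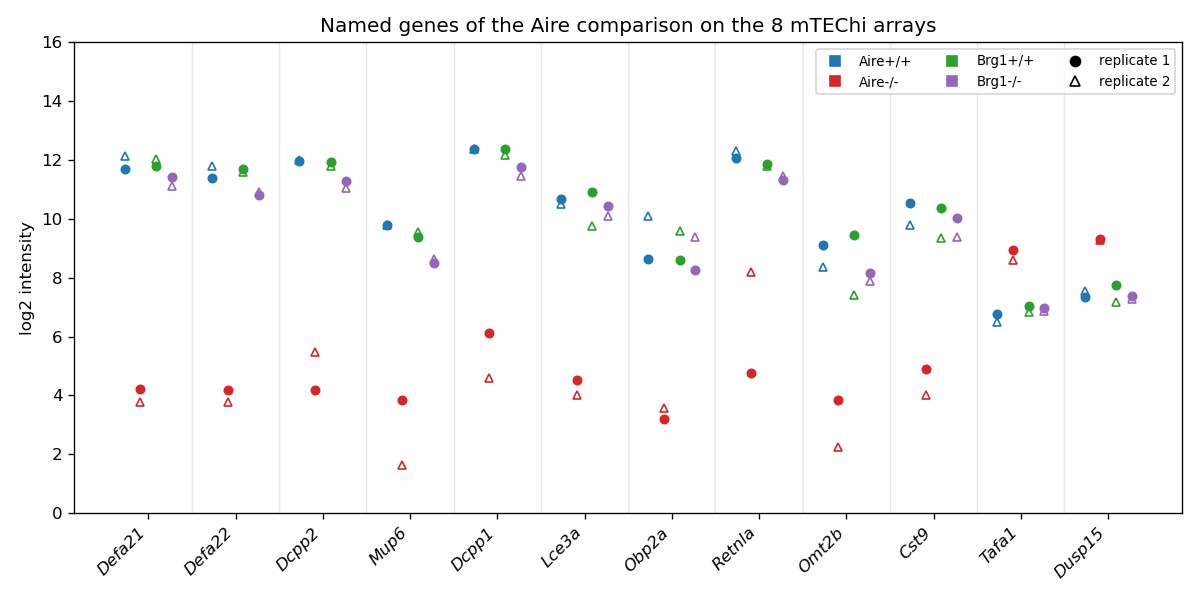
Log2 intensity (vertical axis) of the 12 genes named by the fixed rule in the Aire comparison, on each of the 8 mTEChi arrays. Each point is 1 array, coloured by genotype, with filled circles for replicate 1 and open triangles for replicate 2. The arrays labelled Aire-/- lie apart from the Aire+/+ arrays in every gene shown, which the naming rule required. The differences run from Defa21 (-7.92) to Dusp15 (1.85).

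Genes of the fixed peripheral tissue lists were lower as a group in the arrays labelled Aire-/-. Of the 146 measured genes in the union of 9 tissue lists, 24 fell and 0 rose over all genes tested, and 45 were lower and 1 higher when adjusted over the list alone; the median difference was -0.43 log2 (limma camera adjusted p = 8.25e-29, and adjusted p = 0.0123 with an estimated correlation). Of 16 measured pancreas genes 6 fell (9 adjusted over the list alone), with a list median of -2.34 (limma camera adjusted p = 0.0123 with an estimated correlation). The 6 were the islet hormones Ppy (-4.99), Sst (-2.85) and Iapp (-2.29), the acinar elastase Cela3b (-3.19), Reg3b (-3.54) and Reg1 (-2.78). Of 16 salivary, lacrimal and mammary gland genes 4 fell (8 adjusted over the list alone), among them Obp1a (-5.51), the salivary protein Bpifa2 (-4.03) and the milk casein Csn1s1 (-2.53), with a median of -1.12 (adjusted p = 0.0123 with an estimated correlation). Of 13 stomach genes 2 fell (6 adjusted over the list alone), the gastrokine Gkn2 (-4.75) and the trefoil factor Tff1 (-3.77), with a median of -0.57 (adjusted p = 0.0233 with an estimated correlation). Of 20 intestine genes 3 fell (4 adjusted over the list alone), Defa24 (-5.34), the goblet cell gene Tff3 (-2.87) and the fatty acid-binding protein Fabp2 (-2.50), with a median of -0.51 (adjusted p = 0.0431 with an estimated correlation). Of 20 liver genes 1 fell (4 adjusted over the list alone), the fibrinogen chain Fgb (-3.20), with a median of -0.42 (adjusted p = 0.0167 with an estimated correlation).

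Brain and nerve, retina and lens, and testis and oocyte genes passed camera with the preset correlation but not with an estimated one. With fry the brain and nerve (adjusted p = 0.0468) and retina and lens (adjusted p = 0.0128) lists passed. The testis and oocyte list did not pass with fry (adjusted p = 0.0896). Of 17 brain and nerve genes 4 fell (6 adjusted over the list alone), the neuropeptides Oxt (-4.09), Pmch (-3.44) and Npy (-3.14) and the neurofilament Nefl (-2.64), with a list median of -0.17 (adjusted p = 1.64e-05, and adjusted p = 0.159 with an estimated correlation). Of 14 retina and lens genes 3 fell (4 adjusted over the list alone), the crystallins Cryba1 (-3.99) and Crygs (-3.56) and the retinoid isomerase Rpe65 (-2.09), with a median of -0.10 (adjusted p = 0.000201, and adjusted p = 0.0544 with an estimated correlation). Of 14 testis and oocyte genes 1 fell (2 adjusted over the list alone), the zona pellucida gene Zp3 (-2.74), with a median of -0.14 (adjusted p = 0.00886, and adjusted p = 0.126 with an estimated correlation). None of the 16 muscle genes passed (1 was lower with the replicate block), and the list did not pass (median -0.04, adjusted p = 0.332). The insulin gene Ins2 differed by -0.60 (SE 0.363, adjusted p = 1), and Spt1 was not analysed here.

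Of the lists for mTEC subtypes, signalling and other cells, none held with an estimated correlation. Microfold cell genes had a median of -0.96 (0 of 10 fell, 1 adjusted over the list alone, adjusted p = 4.96e-05, and adjusted p = 0.0671 with an estimated correlation). Cornified keratinocyte genes had a median of -0.47 (0 of 19 fell, 1 adjusted over the list alone, adjusted p = 4.96e-05, and adjusted p = 0.0613 with an estimated correlation). With fry the cornified keratinocyte list passed (adjusted p = 0.0427) and the microfold list did not (adjusted p = 0.1). With the replicate block 3 microfold and 2 cornified keratinocyte genes were lower. Of 17 chemokines and cytokines 1 fell (1 adjusted over the list alone), Xcl1 (-3.94), a chemokine that attracts dendritic cells, with a list median of -0.18 (adjusted p = 0.0229, and adjusted p = 0.17 with an estimated correlation). Interferon response genes had a median of -0.34 (adjusted p = 0.0152, and adjusted p = 0.126 with an estimated correlation) and NF-kB and TNF receptor signalling genes one of 0.32 (adjusted p = 0.0137, and adjusted p = 0.196 with an estimated correlation), with no member past the test in either list. The lists for mTEC maturation (median 0.19, adjusted p = 0.0833, and 0.0438 with the replicate block), tuft cells (-0.02, adjusted p = 0.755), mTEC low or progenitor cells (0.12, adjusted p = 0.655), cortical TECs (0.26, adjusted p = 0.232), SWI/SNF subunits (0.00, adjusted p = 0.775), Aire partners (0.00, adjusted p = 0.82) and the cell cycle (-0.03, adjusted p = 0.755) did not pass. Markers of other cells did not pass camera: thymocytes -0.10 (adjusted p = 0.775), dendritic cells, macrophages and B cells 0.00 (adjusted p = 0.874), and fibroblasts and endothelium 0.11 (adjusted p = 0.232). The fibroblast and endothelium list was higher with fry (adjusted p = 0.0128), and its member Lum differed by 1.39 (SE 0.451, adjusted p = 0.532, and adjusted p = 0.0366 with the replicate block). The p53 response and apoptosis list had a median of 0.12 (adjusted p = 0.863) and the immediate early and heat shock list one of -0.05 (adjusted p = 0.698).

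The second comparison asked which genes in mTEChi depended on Brg1. Of the genes that fell furthest without Aire, none passed the test in Brg1-/- mTEChi: Defa21 differed by -0.65 (SE 0.286), Dcpp2 by -0.70 (SE 0.409), Dcpp1 by -0.67 (SE 0.465) and Mup6 by -0.88 (SE 0.622), each with an adjusted p of 1 (n = 2 and 2). Ins2 differed by -0.28 (SE 0.363) and Aire itself by -0.18 (SE 0.539). With limma 0 of 22154 genes passed, with or without the replicate block, against 1289 and 301 genes at an unadjusted p under 0.05, where 1108 are expected by chance in this and every comparison below. The fit without the block counts the difference between array numbers as spread, so it can be too strict. Without Brg1+/+ mTEChi replicate 2, 1 gene passed, the MHC class II alpha chain gene H2-Ea (7.13, adjusted p = 0.02).

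The fixed lists gave 2 calls for Brg1 in mTEChi, and neither held with an estimated correlation. Thymocyte genes were higher (median 0.27, 0 of 13 past the test, also when adjusted over the list alone, adjusted p = 0.0146, and adjusted p = 0.706 with an estimated correlation). Their most abundant members stood out on 1 array, Brg1-/- mTEChi replicate 2, where Cd3d read 10.12 and Cd8b1 8.92 (log2 intensity). Salivary, lacrimal and mammary gland genes were lower (median -0.25, 0 of 16 past the test, also when adjusted over the list alone, adjusted p = 0.0292, and adjusted p = 0.674 with an estimated correlation). The replicate block added liver genes, lower (median -0.18, adjusted p = 0.0842 without and 0.0411 with the block, and adjusted p = 0.674 with an estimated correlation). Without Brg1-/- mTEChi replicate 2 the number of lists called was 0, and without Brg1+/+ replicate 1 or Brg1-/- replicate 1 it was 1. The union of tissue lists had a median of -0.09 (adjusted p = 0.229), mTEC maturation one of -0.13 (adjusted p = 0.0842) and the SWI/SNF subunits one of -0.03 (adjusted p = 0.568).

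The knockouts were then compared with each other. In the test of the difference itself, the Brg1 effect minus the Aire effect, 30 genes passed, all with the higher value for Brg1 (median 4.83, from 2.91 to 7.27); Defa21 (7.27, SE 0.405, adjusted p = 0.00229), Defa22 (6.84), Dcpp2 (6.46), Dcpp1 (6.36) and Lce3a (6.27) differed most. With the replicate block 201 genes passed, and without single mTEChi arrays the count fell as low as 4, for Aire+/+ replicate 2 and for either Brg1-/- replicate. It was 5 without Aire+/+ replicate 1, 15 without Aire-/- replicate 1 and 13 without Brg1+/+ replicate 2. The pancreas, salivary, lacrimal and mammary gland, and union lists differed between the knockouts with an estimated correlation (each adjusted p = 0.0214). Because 0 genes passed for Brg1 the calls shared 0 genes in either direction. Across the 22154 genes, which are not independent replicates, the Aire and Brg1 effects correlated with r = 0.118 (rho = 0.0543).

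Within pairs of arrays of one number, the Aire effects of the pairs correlated across genes with r = 0.645 (rho = 0.316). The Brg1 effects correlated with r = -0.00723 (rho = -0.0191). For Aire 526 genes were at least 2-fold lower and 66 at least 2-fold higher in both pairs, and for Brg1 19 were lower and 16 higher. At 4-fold the counts were 224 lower and 4 higher for Aire and 4 lower and 0 higher for Brg1. These counts are descriptions without a test.

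**Figure D2:**
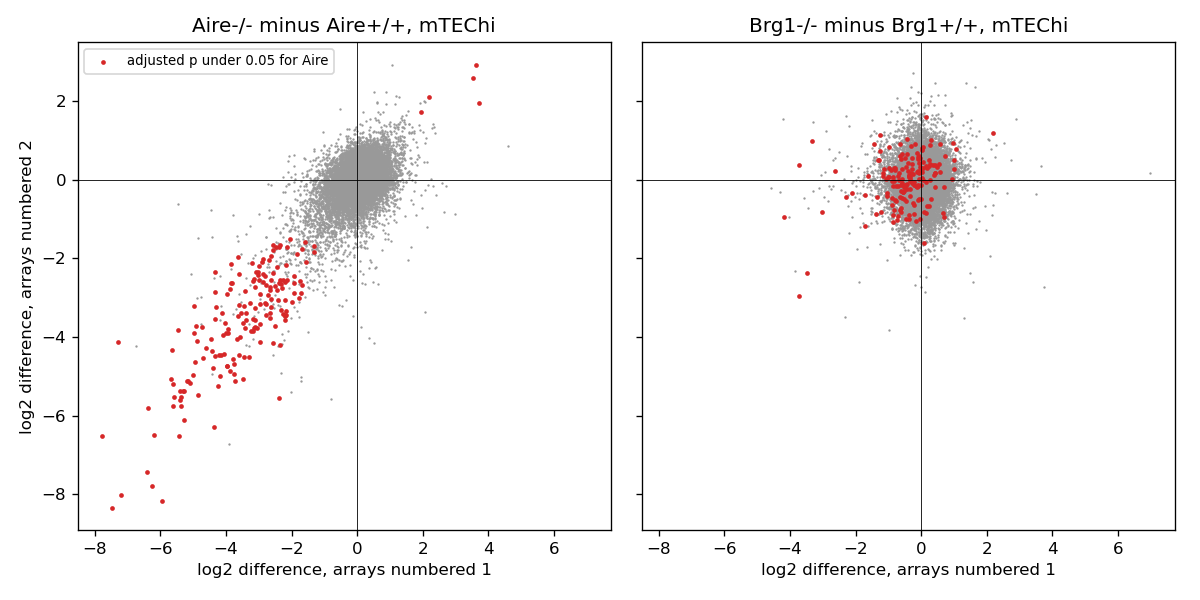
Log2 difference between knockout and wild type in mTEChi, for the arrays numbered 1 (horizontal axis) against the arrays numbered 2 (vertical axis), with Aire on the left and Brg1 on the right. Each grey point is a gene and red points are the 176 genes that passed for Aire. Over all genes the pairs correlated with r = 0.645 (rho = 0.316) for Aire and r = -0.00723 (rho = -0.0191) for Brg1.

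The genes lower without Aire were followed as a set in the other comparisons. In Brg1-/- mTEChi the 171 genes had a median difference of -0.22, with 114 below 0 (limma camera p = 1.11e-06, p = 0.181 with an estimated correlation). Without Brg1+/+ mTEChi replicate 1 the median was 0.07, and without any other single Brg1 mTEChi array it lay between -0.44 and -0.08. Leaving out 1 array leaves the array numbers unbalanced between genotypes, so these shifts can hold the difference between numbers. In Brg1-/- mTEClo the median was -0.45, with 125 below 0 (p = 0.0606 with an estimated correlation), and in Aire-/- mTEClo it was -0.54, with 129 below 0 (p = 0.021 with an estimated correlation). With the replicate block, where the set held 465 genes, the medians were -0.15, -0.25 and -0.31, and the last did not pass with an estimated correlation (p = 0.0735).

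**Figure D3:**
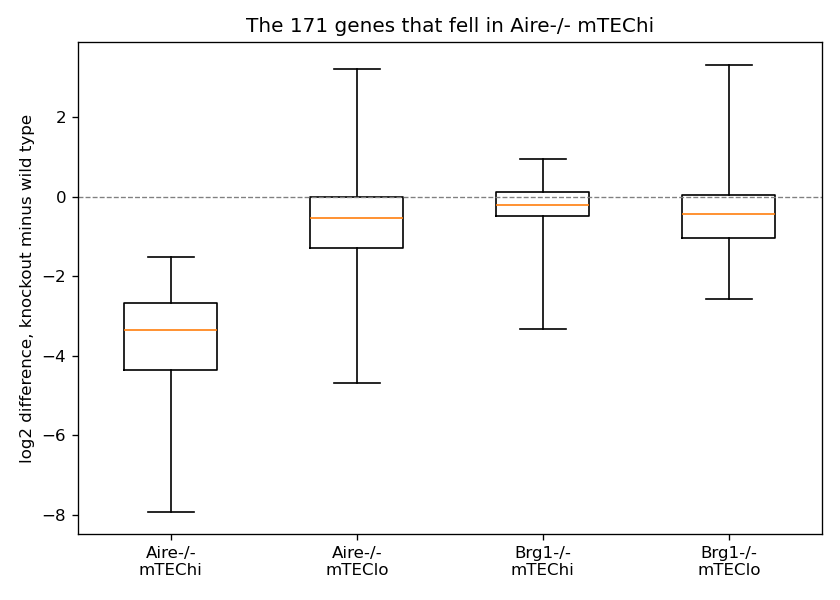
Log2 difference between knockout and wild type (vertical axis) of the 171 genes that fell in Aire-/- mTEChi, in each of the 4 knockout comparisons. Boxes span the quartiles, the line is the median and whiskers reach the lowest and highest gene; the medians are -3.34 (the comparison that chose the genes), -0.54, -0.22 and -0.45.

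The third comparison described how mTEChi differed from mTEClo in the wild types, with the differences of both lines averaged. Both wild-type mTEClo arrays are numbered 1, while the mTEChi arrays carry both numbers. The difference between numbers described below therefore enters these values in part. An example chosen after its values were seen is Tcea1. It read 9.50 and 9.52 on the wild-type mTEChi arrays numbered 1 and 6.43 and 6.58 on those numbered 2. In wild-type mTEClo it read 9.34 and 9.50. Cd80, Cd86 and Cd40, which encode costimulatory molecules, were higher in mTEChi by 3.05 (SE 0.377, adjusted p = 0.0101), 2.45 (SE 0.338) and 1.18 (SE 0.218), with 4 mTEChi and 2 mTEClo arrays. Aire differed by 2.10 (SE 0.467, adjusted p = 0.0743), which did not pass over all genes; it passed with the replicate block (1.67, adjusted p = 0.0123) and when adjusted over the mTEC maturation list alone. Among genes the naming rule allows, the largest rises were in Mup6 (5.24, SE 0.538), Mup20 (5.23), the mast cell protease gene Mcpt2 (5.09, SE 0.24, adjusted p = 0.000993), Csta3 (4.74), the lipocalin Lcn8 (4.64), the kallikrein Klk1b9 (4.64), Pate12 (4.62), Cst10 (4.47), Obp2a (4.47) and Obp1a (4.41). The largest falls were in Ctla2b (-3.35, SE 0.321, adjusted p = 0.00393), the smooth muscle gene Tagln (-3.04, SE 0.314), the taste transducin Gnat3 (-2.88), Mpzl2 (-2.82), the bitter receptor Tas2r109 (-2.78), the tuft cell kinase Dclk1 (-2.58), the fatty acid transporter Cd36 (-2.58), Ctla2a (-2.53), Tas2r118 (-2.44) and Cavin2 (-2.43).

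Of the 22154 genes 567 passed, 427 higher and 140 lower in mTEChi. The median of all genes lay at -0.10 log2, and with each array centred on its median 475 were higher and 121 lower. With the replicate block, which in effect compares arrays of 1 number because all mTEClo arrays are numbered 1, 1534 passed (982 higher and 552 lower), among them all 567. The count was 248 when only the arrays of the groups compared gave the spread. Without Aire+/+ mTEClo it was 80 and without Brg1+/+ mTEClo 130, each being the contrast of the remaining line, and it was 325 and 307 without Aire+/+ mTEChi replicate 1 or 2.

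Of the union of tissue lists 32 of 146 genes rose in mTEChi (52 adjusted over the list alone), with a median of 0.64 (adjusted p = 5.84e-25, and adjusted p = 0.0189 with an estimated correlation); examples were Gkn2 (4.16), Crygs (3.70), Defa24 (3.70), the melanin-concentrating hormone gene Pmch (3.47) and Bpifa2 (3.47). Of its parts, the pancreas (median 1.02), liver (0.81), salivary, lacrimal and mammary gland (1.07), intestine (0.98), stomach (0.60) and testis and oocyte (0.80) lists held with an estimated correlation (adjusted p from 0.0189 to 0.0321). In that order 5, 3, 5, 8, 2 and 3 genes rose over all genes tested, and 8, 8, 9, 9, 4 and 7 adjusted over the list alone. Of 17 chemokines and cytokines 6 rose (9 higher and 1 lower adjusted over the list alone), among them Xcl1 (2.42), Ccl17 (2.27), Tnfsf9 (2.26) and Ccl2 (1.98), with a median of 1.01 (adjusted p = 0.0321 with an estimated correlation). Of 13 tuft cell genes 6 fell (9 adjusted over the list alone), Gnat3, Dclk1, the cytokine Il25 (-2.00), Sh2d6 (-1.99), Ltc4s (-1.56) and Plcb2 (-1.22), with a median of -1.25 (adjusted p = 0.0189 with an estimated correlation). Of 18 mTEC maturation genes 3 rose (8 adjusted over the list alone), with a median of 0.98 (adjusted p = 6.65e-11, and adjusted p = 0.101 with an estimated correlation; median 0.63 with the replicate block).

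Further lists passed for mTEChi against mTEClo with the preset correlation but not with an estimated one. Brain and nerve genes had a median of 0.26 (adjusted p = 0.192 with an estimated correlation), with 3 higher and 4 adjusted over the list alone. Retina and lens genes had one of 0.16 (adjusted p = 0.0949 with an estimated correlation), with 3 higher on either count. The mTEC low or progenitor list, with Fst lower (-2.43), had a median of -0.58 (adjusted p = 0.139 with an estimated correlation), and the SWI/SNF subunits one of -0.34 (adjusted p = 0.202 with an estimated correlation). NF-kB and TNF receptor signalling stood at 0.40 (adjusted p = 0.147 with an estimated correlation), the interferon response at -0.48 (adjusted p = 0.139 with an estimated correlation) and the immediate early and heat shock list at -0.31 (adjusted p = 0.101 with an estimated correlation). Of the markers of other cells, thymocyte genes had a median of 0.41 (adjusted p = 0.395 with an estimated correlation, and adjusted p = 0.189 with the replicate block), dendritic cell, macrophage and B cell genes one of 0.27 (adjusted p = 0.139 with an estimated correlation; 0.11 and adjusted p = 0.0631 with the block), and fibroblast and endothelial genes, with Emcn lower (-2.16), one of -0.33 (adjusted p = 0.101 with an estimated correlation). Aire partners had a median of -0.19 and did not pass as a list, with Sirt1 higher (1.31) and the Ku subunit Xrcc5 lower (-1.96).

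The genes higher in mTEChi of one line were examined under the knockout of the other, so that the levels compared for the list and for the test came from different arrays; the spread was shared by all arrays in the fit. The 75 genes higher in Brg1+/+ mTEChi than mTEClo had a median difference of -1.89 in Aire-/- mTEChi (quartiles -4.38 and -0.16), with 57 below 0 and 38 past the test (limma camera p = 2e-68, p = 0.000506 with an estimated correlation). The 111 genes higher in Aire+/+ mTEChi had a median of -0.13 in Brg1-/- mTEChi, with 62 below 0 and 0 past the test (p = 0.0411, p = 0.41 with an estimated correlation). With each line fitted alone, which shares no spread, the lists held 18 genes (median -4.38 without Aire, p = 0.013 with an estimated correlation) and 2 genes (median -0.15 without Brg1). The 19 genes lower in Aire+/+ mTEChi had a median of -0.12 without Brg1 and the 5 genes lower in Brg1+/+ mTEChi one of -0.36 without Aire, and neither set passed camera. With the replicate block the medians for the higher genes were -0.90 over 429 genes and -0.13 over 500 genes, and the set lower in Brg1+/+ mTEChi held 123 genes with a median of -0.10 without Aire (limma camera p = 0.000654, p = 0.0368 with an estimated correlation). In mTEClo, with 1 array per genotype, the 75 genes had a median of -0.64 without Aire, with 58 below 0 (p = 0.00304 with an estimated correlation), and the 111 genes one of -0.32 without Brg1, with 78 below 0 (p = 0.0263 with an estimated correlation, p = 0.0526 with fry). The replicate block gave -0.17 over 429 genes for Aire (p = 0.033 with an estimated correlation, p = 0.0681 with fry) and -0.21 over 500 genes for Brg1 (p = 0.124 with an estimated correlation). The 123 genes lower in mTEChi in that fit had a median of -0.23 in Aire-/- mTEClo, with 87 below 0. In the main fit this set held 5 genes, with a median of -0.29. On these arrays both sets thus read lower, but 1 array per genotype cannot decide whether the lower values are particular to either set.

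In mTEClo each genotype had 1 array, so these differences have no replicate check and borrow the spread of the mTEChi groups. The acute phase gene Saa2 differed by -5.11 without Aire, the kallikrein Klk1b1 by -4.25 and the C-type lectin Reg3b by -4.04. With limma 0 genes passed for Aire (298 at an unadjusted p under 0.05), and with the replicate block these 3 did. For Brg1 0 genes passed with either fit (382 and 1172 at an unadjusted p under 0.05). Without Aire the microfold list had a median of -1.21, at percentile 0 of 10000 random lists of the same size and mean expression. The pancreas list lay at -0.37 (percentile 0.03), the salivary, lacrimal and mammary gland list at -0.40 (percentile 0), the intestine list at -0.32 (percentile 0.01), chemokines and cytokines at -0.36 (percentile 0.09), the liver list at -0.15 (percentile 2.57) and the union at -0.04 (percentile 2.49), while the muscle list lay at 0.31 (percentile 99.9). Adjusted over the list alone, 4 pancreas genes were lower and 1 gene each of the microfold, salivary and intestine lists. These 8 lists passed camera with the preset correlation and 0 did with an estimated correlation (adjusted p = 0.106 for the microfold, pancreas, salivary, intestine and muscle lists). Without Brg1 the cell cycle list had a median of 0.26 (percentile 99.8, adjusted p = 0.007, and adjusted p = 0.511 with an estimated correlation).

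Whether the effects differed between mTEChi and mTEClo was tested as an interaction. For Aire 0 genes passed with limma (547 at an unadjusted p under 0.05), and 63 did with the replicate block, 60 of them with the lower value in mTEChi. The salivary, lacrimal and mammary gland, retina and lens, and union lists had a lower Aire effect in mTEChi with an estimated correlation (each adjusted p = 0.0492). With fry the retina and lens list did not pass (adjusted p = 0.0695), and the fibroblast and endothelium list was higher (median 0.13, adjusted p = 0.0472; adjusted p = 0.22 with an estimated correlation), with 2 of 15 genes higher adjusted over the list alone. For Brg1 0 genes passed (296 at an unadjusted p under 0.05), and 0 with the replicate block (1133 unadjusted). The cell cycle list had a lower Brg1 effect in mTEChi (median -0.50, adjusted p = 0.0328, and adjusted p = 0.785 with an estimated correlation).

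The wild-type mTEChi groups of the lines were also set against each other. With limma 0 genes passed (240 at an unadjusted p under 0.05), and 0 with the replicate block (1034 unadjusted). As that block is set within each line, its value is the difference at the level of the arrays numbered 1. With a block common to both lines 0 passed (1123 unadjusted). Without Brg1+/+ mTEChi replicate 1, 1 gene passed, H2-Ea (6.84, adjusted p = 0.0262). H2-Ea read 11.42 on Brg1+/+ mTEChi replicate 2, 11.32 and 11.60 on the Brg1-/- mTEChi arrays and 10.11 on Brg1-/- mTEClo, and between 3.98 and 5.89 on the other 8 arrays. Of the lists, 10 passed with the preset correlation, 4 with the replicate block and 0 with an estimated correlation; NF-kB and TNF receptor signalling was higher in Brg1+/+ (median 0.31, adjusted p = 0.00376, and adjusted p = 0.25 with an estimated correlation) and the pancreas list lower (median -0.35, adjusted p = 0.00322, and adjusted p = 0.25 with an estimated correlation; median -0.17 and adjusted p = 0.444 with the replicate block).

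**Figure D4:**
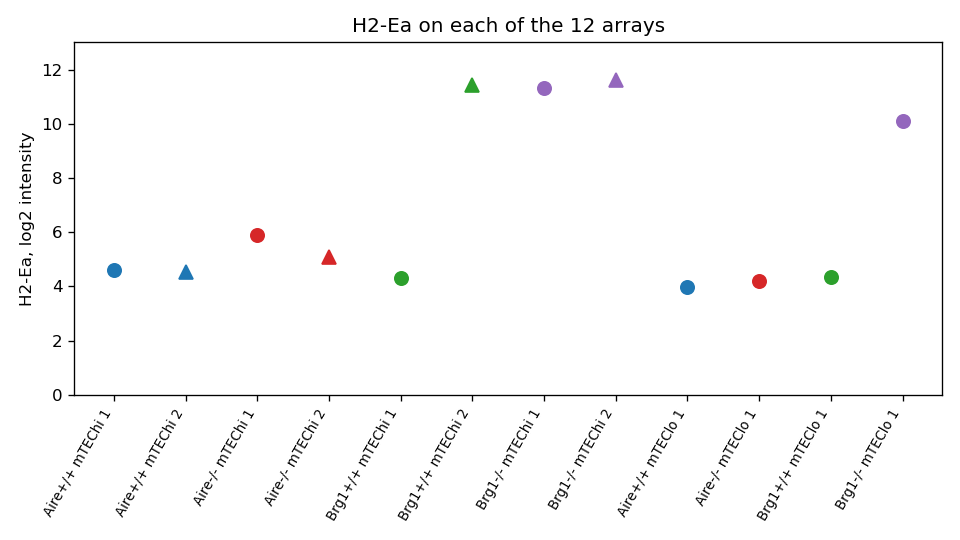
Log2 intensity of H2-Ea (vertical axis) on each of the 12 arrays (horizontal axis), coloured by genotype, with circles for replicate 1 and triangles for replicate 2. The Brg1-/- arrays and Brg1+/+ mTEChi replicate 2 lie between 10.11 and 11.60 and the other 8 arrays between 3.98 and 5.89.

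The arrays numbered 1 and 2 stood apart in every mTEChi group. In all 4 groups alike 307 genes were more than 2-fold higher on array 1 and 120 more than 2-fold higher on array 2, and the transcription elongation factor Tcea1, chosen as an example after its values were seen, read between 9.44 and 9.90 on the arrays numbered 1 in mTEChi and between 6.43 and 6.69 on those numbered 2. The thymocyte gene Cd8b1 read 6.17 and 8.04 on numbers 1 and 2 in Aire+/+, 5.26 and 7.94 in Aire-/-, 6.88 and 7.17 in Brg1+/+ and 5.95 and 8.92 in Brg1-/-. Median intensity was between 5.26 and 5.28 on the first and between 5.07 and 5.12 on the second. Without the genes that differ in this way the interaction of the knockouts gave 47 genes in place of 30. Those genes were chosen for a difference that the main fit counts as spread, so the rise can follow from that choice. Of the sex-linked list, Xist read between 5.27 and 6.79, Eif2s3y between 6.93 and 8.66, Kdm5d between 3.14 and 4.88 and Uty between 3.86 and 5.28, and Ddx3y was not analysed here.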

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

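The tests of a shared batch, of a mislabelled array, of a strain variant, of spread, of Smarca4 loss and of effect size were chosen after the result was seen; the interaction tests were planned, and the outcomes of the tests of normalization, of thymocyte RNA and of antigen-presenting cells were predicted after the pattern was seen but before each test was run.

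The knockouts differed in a test of the difference itself. In mTEChi 30 genes had effects of Brg1 and Aire that differed, led by Defa21 (7.27), Defa22 (6.84), Dcpp2 (6.46), Dcpp1 (6.36) and Lce3a (6.27, log2, Brg1 effect minus Aire effect). Among the lists, 3 differed between the knockouts with an estimated correlation, and 3 had an Aire effect that differed between mTEChi and mTEClo. Outside the tested genes, 69 further probe sets passed for Aire in mTEChi, all 69 lower, of which 30 had no name in the annotation used, 38 had several gene symbols and 1 was a second probe set of a gene.

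No gene passed for Brg1 while 176 passed for Aire. The gap between the effects of the pairs of arrays had a median of 0.36 for Brg1 and 0.28 for Aire, a ratio of 1.29, which lies between the bounds set for and against a larger spread. On the Brg1-/- mTEChi arrays 55.5 percent of the Smarca4 signal was left, but where the probe set lies relative to the deleted part is not known, so incomplete loss of the RNA remains open. The count of genes at least 4-fold lower in both pairs, which uses no estimate of spread, was 4 against 224 for Aire; it goes with a smaller effect of Brg1 loss but comes from the same arrays and does not give the cause. Differences between the lines in timing of deletion or in residual protein were not tested.

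H2-Ea was high on 4 arrays and low on 8. As background, mice of the H2-b haplotype, such as C57BL/6, carry a deletion that silences this gene. The high readings on 4 arrays do not go with that deletion in all mice, so the C57BL/6 description may not hold for each mouse. RNA of antigen-presenting cells was argued against. Over the 2 contrasts of high and low arrays numbered 1, in mTEChi and in mTEClo, the median of 14 of their markers was -0.02. H2-Ea differed by 6.99 in the mTEChi contrast and read 10.11 against 4.35 in the mTEClo contrast. A mislabelled Brg1+/+ mTEChi replicate 2 cannot be told apart from a correct label by Smarca4, which read 6.89 there against at most 5.88 on the Brg1-/- mTEChi arrays, since that probe set is not known to lie in the deleted part. Such a mislabel alone would leave H2-Ea high on the arrays labelled Brg1-/-, at 11.32 and 11.60 in mTEChi and 10.11 in mTEClo. The Brg1 contrast in mTEChi holds this difference in part, since Brg1+/+ mTEChi replicate 1 read 4.33. A strain variant near H2-Ea may be carried by some mice of the Brg1 line, as the 12 values have a gap of 4.22 between levels. No genotype was analysed here, so the gap cannot decide this, and no further explanation was tested.

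The arrays numbered 1 and 2 differed alike in all 4 mTEChi groups. Uneven quantiles of the arrays as the whole cause were argued against, since 316 of the 427 genes stayed beyond 2-fold in all groups after a further quantile normalization. That step cannot remove shifts of single probe sets, so it cannot decide whether arrays of each number were normalized separately. Thymocyte RNA on the arrays numbered 2 was argued against only as the whole cause, since mTEC maturation genes had a median of 0.32 (array 2 minus array 1) where the 307 lower genes had one of -1.56; as a part it remains open, although the cells were sorted as CD45-negative and Epcam-positive, since thymocyte genes had medians of 0.30, 0.27, 0.02 and 0.43 in Aire+/+, Aire-/-, Brg1+/+ and Brg1-/-. A batch shared by the arrays of a number is consistent with the mTEClo arrays, all numbered 1, of which the lowest had 87.6 percent of those genes nearer to the mTEChi arrays numbered 1. What the number stands for, and whether it names a day, litter or amplification, is not given, and no further explanation was tested.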

How the results depend on the processing

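The common block, the leave-one-out of list tests and of the overlap, the tests without the genes that differ between array numbers, the tests of the set lower without Aire, the mTEClo tests of genes higher in mTEChi and the fits of each line alone were chosen after the data were seen. The replicate numbers pair only 2 arrays per group, and what the number stands for is not given. The difference of array 1 and array 2 correlated across genes between the 4 mTEChi groups with r from 0.552 to 0.657. The main fit counts this difference as spread. Its genes at an unadjusted p under 0.05 were 301 for Brg1 in mTEChi and 240 for the wild types, where 1108 are expected by chance. With the block within each line they were 1289 and 1034, the second for the difference at the level of number 1. With a block common to both lines they were 1455 and 1123. The main fit is therefore likely too strict in these comparisons, and its counts of genes passing are not well calibrated. With the replicate block the genes passing were 531 for Aire in mTEChi, 1534 for mTEChi against mTEClo, 3 for Aire in mTEClo, 201 for the difference of the knockouts and 63 for the difference of the Aire effects; with a block common to both lines they were 569, 1757, 7, 228 and 66. The block's construction removes the difference between numbers from the spread; the other causes were not tested. With the spread of only the arrays compared 248 genes passed for mTEChi against mTEClo; this fit leaves no residual degrees of freedom for mTEClo alone, so it gives no value there, and the fit of the 6 arrays of a line gave 0 for both knockouts in mTEClo. Aire in mTEClo gave 1 gene after quantile normalization and 2 among genes above the middle of mean values, where the difference of the knockouts gave 46, and 47 without the genes that differ between numbers. Leaving out 1 array gave 53 to 70 genes for Aire in mTEChi, 0 to 1 for Brg1 (H2-Ea), 80 to 470 for mTEChi against mTEClo, 4 to 28 for the difference of the knockouts and 0 to 1 for the wild types (H2-Ea); lone arrays were assumed to vary like the other groups. Of the 176 Aire calls 52, 62, 66 and 66 were kept, and 0 changed sign. The overlap of calls was 0 under every alternative run and is bounded by the 0 or 1 Brg1 calls. With an estimated correlation the lists called fell from 14 to 6 for Aire in mTEChi, 2 to 0 for Brg1 in mTEChi, 20 to 9 for mTEChi against mTEClo, 8 to 0 and 1 to 0 in mTEClo, 14 to 3 for the difference of the knockouts, 8 to 3 and 1 to 0 for the interactions with cell type, and 10 to 0 for the wild types. With fry they were 0 for Brg1 in mTEChi, 0 for both knockouts in mTEClo, 5 for the difference of the knockouts, 3 for the Aire interaction and 0 for the Brg1 interaction and the wild types; with the replicate block they were 2 for Brg1 in mTEClo and 4 for the wild types. Without 1 array they were 11 to 14 for Aire, 0 to 2 for Brg1 and 16 to 19 for mTEChi against mTEClo. The Brg1 effect on genes higher in mTEChi (-0.13) and the effects on the genes lower without Aire of Brg1 in mTEChi (-0.22) and mTEClo (-0.45) did not pass with an estimated correlation or fry, nor did that of Aire in mTEClo (-0.54) or the Brg1 effect in mTEClo on genes higher in mTEChi (-0.32) with fry. With each line fitted alone the Aire and Brg1 effects on genes higher in mTEChi were -4.38 over 18 genes and -0.15 over 2 genes, and the second did not pass. The Aire effect on genes lower in mTEChi (-0.36 over 5 genes, not past camera) passed with the replicate block (-0.10 over 123 genes). Without Brg1+/+ mTEChi replicate 1 the effect of -0.22 reversed to 0.07, and over the 4 Brg1 mTEChi arrays it ranged from -0.44 to 0.07. Leaving out 1 mTEChi array leaves the array numbers unbalanced between groups. These changes, and the counts given above without 1 array, can therefore hold the difference between numbers. All other counts listed in the table of alternatives stayed within 1.5 times the main value, and all other set effects there kept their direction and side of the threshold; of the values of single named genes, 1846 kept both, 120 newly passed, 49 no longer passed and 0 reversed. Signal over background is not known, so differences of dim genes are bounded by an unknown floor.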

Other observations

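The gene families below were chosen after their values were seen, and their counts are over all genes tested.

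Among families of secreted proteins, 6 of 10 Defa defensin genes fell in the arrays labelled Aire-/- (median -3.77 log2), and 6 of 10 rose in mTEChi against mTEClo (median 2.46). Of 42 Defb defensin genes 8 fell without Aire (median -0.88) and 10 rose in mTEChi (median 0.83). The lipocalins (Lcn) gave 5 of 10 lower without Aire and 5 higher in mTEChi, the secretoglobins (Scgb) 5 of 23 and 5, the Reg lectins 3 of 6 and 4, the cystatins (Cst) 3 of 12 and 6, and all 3 Dcpp genes were lower without Aire and higher in mTEChi. The Klk1b kallikreins gave 7 of 11 higher in mTEChi (median 2.51) and 1 lower without Aire (median -1.05), and with the replicate block 10 and 5. The other families looked at gave the following counts. Lower without Aire were 2 of 18 Lce, 0 of 12 Sprr, 1 of 12 Pate, 1 of 5 Csn, 2 of 7 Svs, 2 of 5 Mup and 2 of 4 Obp genes. Higher in mTEChi, in that order, were 1, 1, 5, 2, 2, 2 and 2. The Lce median was -1.71 without Aire, where 10 of the 18 genes were lower with the replicate block, and -0.38 in mTEChi against mTEClo. In Brg1-/- mTEChi 0 of all 22154 genes passed with limma, with or without the replicate block, so no family could hold a call. The Defa and Klk1b medians there were -0.29 and -0.46. Members of a family can be similar in sequence, so probe sets can read more than 1 gene and the counts should not be taken as counts of independent genes.

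Of 35 measured bitter taste receptor genes (Tas2r) 10 were lower in mTEChi than in mTEClo (17 with the replicate block), with a median of -0.86, beside the tuft cell genes Gnat3 (-2.88) and Dclk1 (-2.58). Without Aire 0 of the 35 passed in mTEChi, with or without the block, and their median was 0.24; without Brg1 it was -0.01.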
